A study of Homo sapiens with 4 samples.

How the data were processed

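RNA purified on poly(T) beads, per the labels' protocols, was sequenced in 4 libraries of MDA-MB-231, an established human line of triple-negative, mesenchymal-like breast cancer cells. Of these, 2 libraries came from cells labelled wild type and 2 from cells labelled NatD knockout. NatD knockout cells were made by infection with lentivirus, per the labels' protocols. The labels give CRISPR as the treatment of all 4 samples, and do not say what the wild type cells received. NatD is the enzyme that acetylates the N-terminus of histones H4 and H2A, and its gene is NAA40. The deposited table gives gene expression as FPKM (fragments scaled by transcript length and by the number of mapped fragments), as computed by the authors, with 1 value per gene and library. The genome build was hg38, per the submitters' processing notes. The aligner, the quantifier and the gene annotation are not given in the sources used here. The table lists 17772 genes by symbol, and every listed gene has a value above 0 in at least 1 library. It holds no mitochondrially encoded gene of the list written for them, so that sign of RNA quality was not available. No counts are given, and the deposited values are estimates with many digits, so the absolute depth of each library is unknown and no counting interval is given. Among genes at very low values, ratios between libraries piled up at a single value. At that value wild type replicate 2 was 1.09 times as deep as wild type replicate 1, NatD knockout replicate 1 was 0.920 times as deep, and the ratio for NatD knockout replicate 2 was 1. These are relative depths only.

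Each gene's locus is given as the deposited table gives it. In the table the start was 1 below the start in the RefSeq annotation of GRCh38 for 2547 tested genes and equal to it for 319, so starts were read as counted from 0 and are printed counted from 1. A locus can span several overlapping genes. Of the genes called below, 23 share their locus with at least 1 other listed gene, and since nothing states that strand was kept, reads of overlapping or antisense partners cannot be told apart there. Genes with near-identical copies, such as HLA-DRB1 and HLA-DRB5, CST1, CST2 and CST4, and the histone genes, are uncertain as single genes because the counting could split reads between copies.

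Values were analysed as log2(FPKM + 1), that is, with a pseudocount of 1. Fold changes on this scale understate the change of genes at low values. The 12554 genes with an FPKM of at least 0.5 in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model for the knockout effect, empirical Bayes moderation with a variance trend, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was called. Nothing in the labels says that the 2 libraries of a group came from separate cultures, clones or guide RNAs, so p-values measure only the spread between these libraries, which may be technical. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so each call rests on variance information shared across genes. On simulated data with the same genes and 200 changed genes, the fit recovered 37.5% of genes changed by 1 on the log2 scale. It recovered 94.5% of those changed by 2 and 98.5% of those changed by 3, and 6.09% of its calls were false. The simulation gave both groups the same spread, drawn from the model's own fit. A wider spread of 1 group or a GC trend was not simulated, so these shares are not error rates of the calls below.

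Before the data were examined, 33 gene lists were written down (pathways, complexes and cell type markers that fit this cell line and enzyme), and 31 had the 3 tested members needed. They were tested with camera, a competitive test of a list against all other genes, at a preset correlation between genes of 0.01, and adjusted over the lists. The same test with a correlation estimated from these libraries, and fry, a test of whether a list's genes move on balance one way, were run as alternatives. With an estimated correlation, camera rests on the 2 residual degrees of freedom of these libraries, so a list can hardly pass. A call lost in that setting therefore does not show that correlation between genes made the call. The choice of genes named in the text was also fixed. It takes NAA40, then the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap and whose mean FPKM was at least 5 in the higher group. For each list it takes up to 4 called members with the largest change, or the 2 with the smallest p where none was called. FOXA2, SNAI2 and MMP14 are given whatever their values.

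The alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean FPKM of 5, scaling by median ratios, rescaling to TPM, quantile normalization, a variance prior without a trend or made robust, the replicate number as a block, a minimum change of 1 on the log2 scale, and leaving out each library in turn. A correction for transcript length and GC content, and group weights that let the knockout libraries vary more, were added after the data had been seen. So was a fit without the genes of shifted chromosome regions, which were defined as at least 3 neighbouring runs of 50 tested genes whose median differed from the wild type mean by at least 0.15 on the log2 scale, in the same direction in both knockout libraries. A second such fit also left out the regions that met this rule after the length and GC correction. Length and GC content were taken from the longest GENCODE 29 transcript of the same gene name and were found for 94.8% of the tested genes. Figures were drawn with matplotlib 3.10.9.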

Results

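Gene expression was compared between MDA-MB-231 breast cancer cells labelled wild type (n = 2 libraries) and MDA-MB-231 cells labelled NatD knockout (n = 2 libraries), to ask which transcripts differ between them. NatD is a histone N-terminal acetyltransferase, and its loss in the cells labelled knockout is taken from the labels. The libraries held between 11104 and 11569 genes at an FPKM of at least 1. The wild type pair was tight, with 15 of 12554 tested genes at least 2-fold apart on the log2(FPKM + 1) scale and a standard deviation of the log2 difference of 0.151. The knockout pair was looser, with 199 genes at least 2-fold apart and a standard deviation of 0.421. Knockout replicate 1 stood apart by GC content. In the fifth of genes with the lowest GC content (median 38.6%) its median was 0.36 above the wild type mean on the log2 scale, and in the fifth with the highest (median 61.7%) it was at -0.16. For knockout replicate 2 these medians were -0.14 and -0.01. 18S ribosomal RNA (RNA18S5) stood at 1757 and 2360 FPKM in wild type replicates 1 and 2, and at 1507 and 3481 in knockout replicates 1 and 2.

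**Figure D1:**
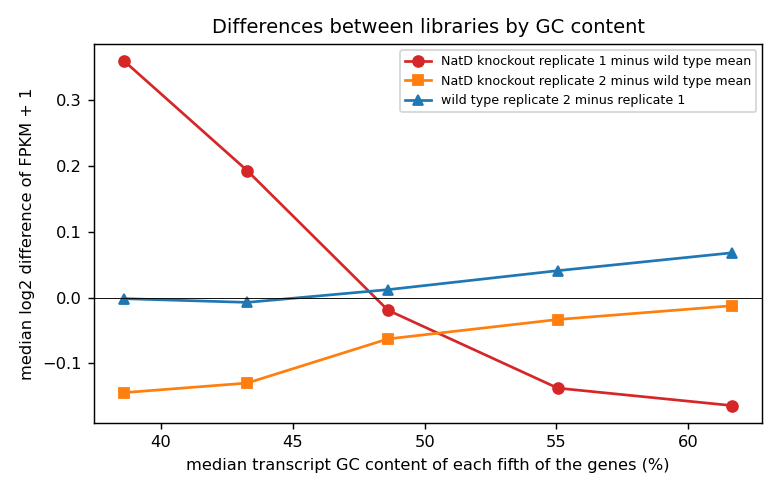
Median log2 difference of FPKM + 1 between libraries (y axis) in 5 equal groups of genes ordered by transcript GC content (x axis, median percent of each group). The line for knockout replicate 1 runs from 0.36 at 38.6% GC to -0.16 at 61.7% GC, while that for knockout replicate 2 runs from -0.14 to -0.01.

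The targeted gene was examined first. NAA40 (chromosome 11, 63938970 to 63957319, hg38) had an FPKM of 8.09 and 8.44 in wild type replicates 1 and 2, and of 5.19 and 7.09 in knockout replicates 1 and 2. The knockout libraries thus held 62.8% and 85.8% of the wild type mean. The log2 fold change of -0.39 ± 0.20 (SE, n = 2 per group) did not pass the test (limma, adjusted p = 0.469). The position of the guide RNA is not given in the sources used here, and a CRISPR edit can leave a gene's mRNA in place, so the mRNA level neither supports nor contradicts the labels.

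Between the libraries labelled NatD knockout and those labelled wild type 117 genes changed, of which 91 fell and 26 rose (limma, adjusted p under 0.05), and 115 of them changed by at least 1 on the log2 scale. The strongest falls were in CST1 and CST4, secreted cysteine protease inhibitors, in the MHC class II genes HLA-DRB1, HLA-DRA, HLA-DRB5 and HLA-DPA1, in the transcription factors SPDEF and FOXA2, and in PTGES and SCD, enzymes of prostaglandin E2 and monounsaturated fatty acid synthesis. The strongest rises were in INHBA, the subunit of activin A, in the connexin gene GJB3, in LCN2, a secreted siderophore-binding protein, and in CYP24A1, which inactivates vitamin D. The number of calls depends on the treatment of variance and scale. It was 12 after rescaling to TPM, 349 (126 higher and 223 lower, so 36.1% higher against 22.2% of the 117) after a correction for length and GC content, and 0 without a filter on low values (limma, 2272 genes at an unadjusted p under 0.05). With knockout replicate 1 left out it was 5585 (1980 higher and 3605 lower) and with knockout replicate 2 left out 6548 (3522 higher and 3026 lower), where the spread comes from the wild type pair alone. Without knockout replicate 2 falls thus did not predominate among all calls, a far larger set that is not comparable with the 117. Among changes of at least 2-fold on the log2(FPKM + 1) scale, falls were more frequent. Of the tested genes, 105 were that much lower and 29 that much higher in each knockout library than in each wild type library. Of the 3125 genes called in both of these fits, 2273 had the same direction and 852 opposite directions. Independent lists of the same sizes would share 1424 and 1489, and part of the excess in the same direction may come from the shared wild type libraries. In 20 simulations of unchanged libraries with the spread of the wild type pair, 0 genes were called in both, but the knockout pair's wider spread was not simulated.

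Genes of 2 chromosome regions lay apart from the rest in both knockout libraries. On chromosome 10 (78033760 to 133424617), which holds SCD, IFIT2, IFIT3, DUSP5 and ANKRD1, 194 of 249 tested genes were lower than the wild type mean in both, with a median of -0.35 in knockout replicate 1 and -0.53 in replicate 2. On chromosome 15 (64963021 to 100916625), which holds TIPIN, KIF23, PRC1, FANCI and FAM174B, 141 of 200 were higher in both, with medians of 0.32 and 0.22. The difference between the wild type libraries had medians of 0.01 and 0.02 there. With length and GC corrected, the medians in knockout replicates 1 and 2 were -0.39 (bootstrap 95% interval -0.46 to -0.35) and -0.39 (-0.45 to -0.36) on chromosome 10, and 0.32 (0.27 to 0.36) and 0.35 (0.30 to 0.39) on chromosome 15. The regions were defined after the data had been seen, and 0 of 100 shuffled gene orders gave such a region. Shuffling breaks every likeness between neighbouring genes, that of GC content included, so this count does not tell why these regions lay apart. The intervals of all regions given here come from resampling the genes of a region that was chosen for its shift. They are not adjusted for that choice, treat neighbouring genes as independent and measure no spread between libraries. They hold 10 of the 117 changed genes, 9 lower on chromosome 10 and FAM174B, higher, on chromosome 15. With length and GC corrected, 2 regions of chromosome 1 met the same rule. In the first (11874 to 32060859, 300 tested genes) the corrected medians in knockout replicates 1 and 2 were 0.24 (0.21 to 0.27) and 0.41 (0.34 to 0.45), and in the second (36339619 to 70368022, 200 tested genes) 0.23 (0.20 to 0.28) and 0.38 (0.33 to 0.45). The first holds 1 called riser and 3 called fallers, and the second the riser PDZK1IP1 and the faller PCSK9.

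CST1 (chromosome 20, 23747553 to 23750937) fell from 122.8 ± 5.14 FPKM to 1.83 ± 1.28 (SD, n = 2 each), a log2 fold change of -5.53 ± 0.31 (SE, limma adjusted p = 0.00920). Its neighbour CST4, a near-identical cystatin gene, fell by 3.10 on the log2 scale, from 38.9 to 4.13 FPKM. SPDEF (chromosome 6, 34537802 to 34556333), an ETS factor of secretory and luminal epithelium, fell from 11.7 ± 0.152 to 0.455 ± 0.381 FPKM (log2 fold change -3.15 ± 0.23, limma adjusted p = 0.0108). FOXA2 (chromosome 20, 22581004 to 22585463), a pioneer transcription factor of endoderm, fell from 8.07 ± 0.625 to 0.277 ± 0.0260 FPKM, which is 29.2-fold lower (log2 fold change -2.83 ± 0.17, limma adjusted p = 0.00920). PTGES (chromosome 9, 129738336 to 129753065) fell from 77.05 ± 0.960 to 8.67 ± 1.79 FPKM, 8.89-fold lower. LINC01296, a long non-coding RNA whose locus overlaps other listed genes, fell by 2.63 on the log2 scale, and GGT5, a gamma-glutamyltransferase, fell by 2.43.

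Among the risers, INHBA (chromosome 7, 41689003 to 41779378) went from 10.0 ± 0.215 to 52.6 ± 12.8 FPKM, 5.24-fold higher (log2 fold change 2.26 ± 0.19, limma adjusted p = 0.0150). LCN2 (chromosome 9, 128149453 to 128153455) went from 148.6 ± 2.35 to 581.7 ± 7.89 FPKM, 3.92-fold higher, with close agreement between the knockout libraries (log2 fold change 1.96 ± 0.13, limma adjusted p = 0.00920). GJB3 rose from 1.26 to 9.76 FPKM and CYP24A1 from 2.91 to 13.8 FPKM. The non-coding RNA genes UCA1 and FLJ22447 rose by 1.76 and 1.58 on the log2 scale, and the membrane protein gene PDZK1IP1 by 1.66. The corepressor gene TLE2 rose by 1.60, FAM174B by 1.51, and the focal adhesion scaffold gene NEDD9 rose from 15.9 to 47.2 FPKM. EPCAM and ESRP2 are given with the epithelial genes below. The loci of INHBA, TLE2, FLJ22447 and ESRP2 each hold 1 other listed gene.

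**Figure D2:**
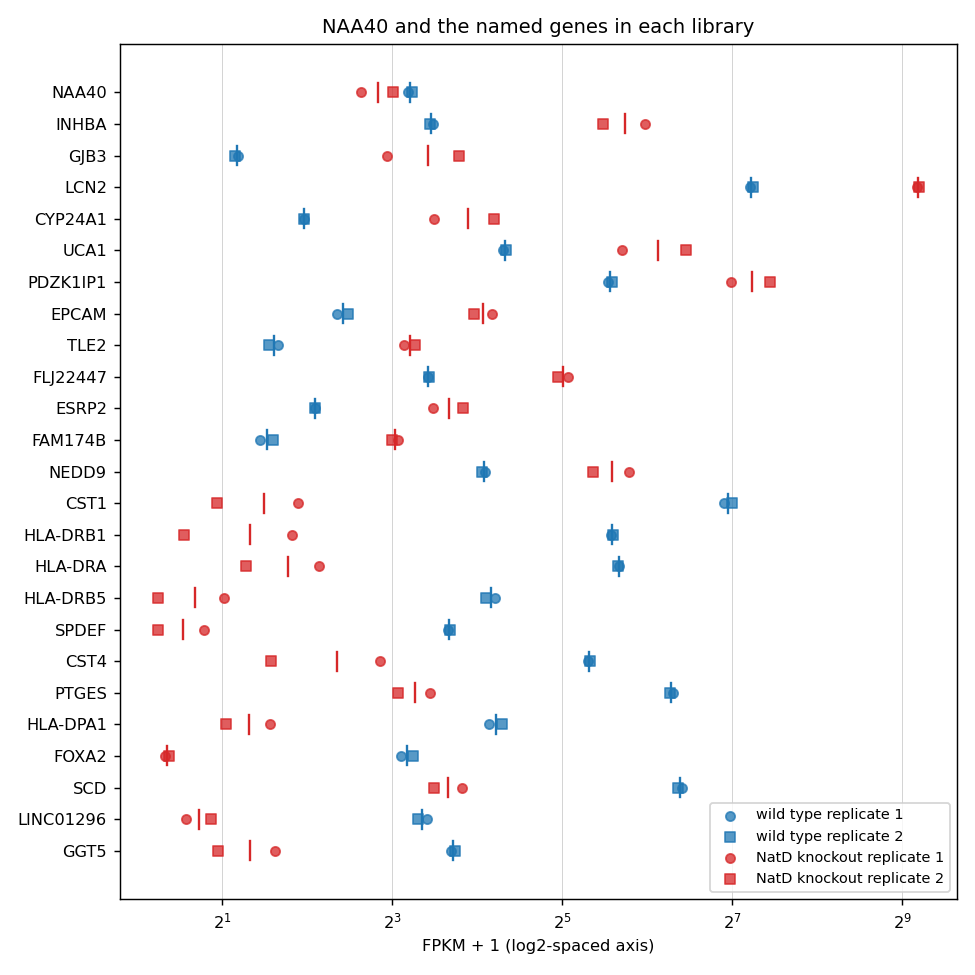
FPKM + 1 (x axis, log2-spaced) of NAA40 and of the 24 genes with the largest changes in each of the 4 libraries (points), with the mean of each group as a vertical bar. For the 24 genes the knockout points lie clear of the wild type points, as for LCN2 at 576 and 587 FPKM against 147 and 150, while NAA40 at 5.19 and 7.09 lies close to 8.09 and 8.44.

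The lists of antigen presentation and interferon-stimulated genes were called lower (camera, adjusted p = 7.73e-15 and 2.14e-10). With a correlation estimated from these libraries neither was called (adjusted p = 0.445 and adjusted p = 0.499 with an estimated correlation), nor by fry (adjusted p = 0.0718 and 0.163). Of 23 tested antigen presentation genes, 8 fell, none rose, and all 23 had a log2 fold change below 0 with a median of -0.62. Adjusted over the list alone, 14 fell. HLA-DRB1 fell from 47.1 ± 0.651 to 1.51 ± 1.48 FPKM, and HLA-DRA (chromosome 6, 32439842 to 32445051), which has no near-identical copy, from 49.8 ± 0.363 to 2.43 ± 1.39 FPKM (log2 fold change -3.95 ± 0.29, limma adjusted p = 0.0108). HLA-DPA1 fell by 2.91 on the log2 scale, and HLA-DMB, which helps load class II peptides, fell by 2.13. The MHC class I genes HLA-A, HLA-B and HLA-C did not pass (limma, adjusted p = 0.760, 0.658 and 0.393), with HLA-A at 1289 ± 16.3 FPKM in wild type and 1155 ± 124.9 in knockout. These 3 genes were chosen after their values were seen. Of 34 tested interferon-stimulated genes, 5 fell and none rose (13 fell adjusted over the list alone), with a median of -0.44. OASL fell from 4.53 to 0.200 FPKM, IFIT3 from 11.9 to 2.31, OAS2 from 6.45 to 1.35 and IFIT2 from 3.70 to 0.552. The interferon median was -0.27 in knockout replicate 1 and -0.67 in replicate 2, and the antigen presentation median -0.60 and -0.70.

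The lists of inflammatory, cholesterol and fatty acid genes were called lower (camera, adjusted p = 3.17e-05, 5.98e-05 and 0.0223). With an estimated correlation none was called (adjusted p = 0.499, adjusted p = 0.445 and adjusted p = 0.445 with an estimated correlation). Of 28 tested inflammatory cytokine and NF-kB target genes, 1 fell and 1 rose, and 25 lay below 0 with a median of -0.53. Adjusted over the list alone, 11 fell and 3 rose. CSF1, the macrophage growth factor, fell from 234.7 ± 9.56 to 44.7 ± 15.55 FPKM, 5.25-fold lower, whereas IL1A rose from 9.36 ± 0.596 to 28.4 ± 4.55. CSF1 lies in a run of 50 tested genes (chromosome 1, 108746663 to 113812476) that was lower in both knockout libraries. The medians of this run were -0.34 and -0.48 in knockout replicates 1 and 2. The rule for shifted regions, which asks for 3 neighbouring runs, leaves it out. Of 28 cholesterol synthesis and uptake genes, 2 fell and none rose (7 fell adjusted over the list alone). These were PCSK9, which promotes degradation of the LDL receptor, from 4.27 to 0.132 FPKM, and SREBF2 (chromosome 22, 41833079 to 41907308), the transcription factor of the pathway, from 37.9 ± 1.02 to 16.4 ± 1.09 FPKM. Of 21 fatty acid genes, 2 fell and none rose (6 fell adjusted over the list alone). SCD (chromosome 10, 100347015 to 100364831), the desaturase that makes oleate, fell from 82.6 ± 1.999 to 11.7 ± 2.01 FPKM, 7.08-fold lower (log2 fold change -2.73 ± 0.16, limma adjusted p = 0.00920), and FADS2 from 65.2 to 29.1. The fatty acid list was the only one called by fry (adjusted p = 0.0140), but with knockout replicate 1 left out it was lost in camera (adjusted p = 0.284), as it was with the shifted regions of chromosomes 10 and 15 left out (adjusted p = 0.140) and with those of chromosome 1 left out too (adjusted p = 0.0890).

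The lists of extracellular proteases and inhibitors and of integrins and focal adhesion were called lower (camera, adjusted p = 0.000205 and 0.0433). With an estimated correlation neither was called (adjusted p = 0.499 for each with an estimated correlation), nor by fry (adjusted p = 0.163 and 0.198). Of 25 tested extracellular protease and inhibitor genes, 2 fell and none rose, with a median of -0.42 (12 fell and 1 rose adjusted over the list alone). The interstitial collagenase gene MMP1 fell from 8.08 ± 1.19 to 0.941 ± 0.109 FPKM, and its locus overlaps other listed genes. TIMP3, an inhibitor of such proteases, fell from 81.9 ± 1.08 to 35.9 ± 5.64. Of 27 integrin and focal adhesion genes, 2 fell, both adjusted over all genes and over the list alone. These were the integrin genes ITGB3, from 3.17 to 0.688 FPKM, and ITGB2, from 2.06 to 0.265. The integrin call was also lost with either knockout library left out (camera, adjusted p = 0.0745 and 0.137), at pseudocounts of 0.1 and 0.5 (adjusted p = 0.0718 and 0.0530), at a mean FPKM of at least 5 (adjusted p = 0.160), after rescaling to TPM (adjusted p = 0.0737) and with the regions of chromosomes 1, 10 and 15 left out (adjusted p = 0.0513). Of 28 collagen, laminin and matrix genes, 2 rose and none fell, and the list was not called (camera, adjusted p = 0.425). THBS1, encoding thrombospondin 1, rose from 339.0 ± 10.1 to 853.5 ± 20.5 FPKM and COL12A1 from 21.1 ± 0.741 to 44.6 ± 0.987. Adjusted over the list alone, 2 rose and 3 fell.

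The list of epithelial genes was called higher (camera, adjusted p = 0.000409), and that of mesenchymal genes was not called (camera, adjusted p = 0.316). The epithelial call was lost with an estimated correlation (adjusted p = 0.445 with an estimated correlation), in fry (adjusted p = 0.159) and with knockout replicate 2 left out (camera, adjusted p = 0.213). Of 22 tested epithelial genes, 3 rose and 1 fell, with a median of 0.32 (5 rose and 1 fell adjusted over the list alone). EPCAM, the epithelial adhesion molecule, rose from 4.35 ± 0.352 to 15.8 ± 1.76 FPKM (log2 fold change 1.65 ± 0.17, limma adjusted p = 0.0236). ESRP2, a splicing regulator of epithelial cells, rose from 3.26 to 11.8 and the protease inhibitor gene SPINT1 from 5.23 to 13.6, while the tight junction gene CLDN7 fell from 24.6 to 8.30. Of 23 mesenchymal genes, TGFBI rose from 76.2 to 144.7 FPKM and S100A4, a calcium-binding protein of motile cells, fell from 361.2 ± 8.22 to 74.9 ± 38.9 FPKM. Adjusted over the mesenchymal list alone, 2 rose and 1 fell. Of 12 luminal breast genes, markers of the MCF7 line that the labels' protocols also mention, 2 fell and none rose. These were SPDEF and AGR2, which was at 0.996 and 1.02 FPKM in the wild type libraries and listed at 0 in both knockout libraries. The luminal list was not called (camera, adjusted p = 0.143), but it was called lower with wild type replicate 1 or 2 left out (camera, adjusted p = 0.00289 and 0.00567) and with the replicate number as a block (adjusted p = 0.00339). Adjusted over the list alone, 1 rose and 4 fell.

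**Figure D3:**
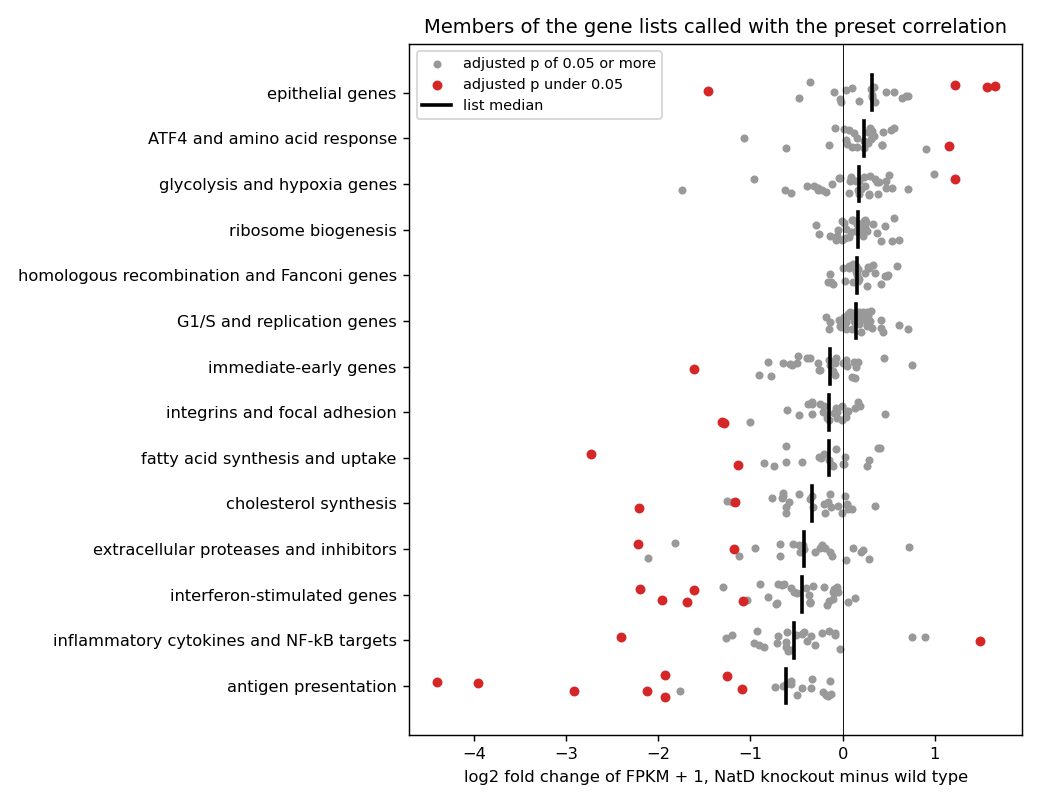
Log2 fold change of FPKM + 1, NatD knockout minus wild type (x axis), of each tested member (points) of the 14 lists called with the preset correlation (y axis), with list medians as black bars and genes past an adjusted p of 0.05 in red. Medians run from -0.62 for antigen presentation to 0.32 for epithelial genes. With an estimated correlation 0 of the 14 lists were called, a setting in which a list can hardly pass with 2 libraries per group.

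The lists of G1/S and replication, recombination, ribosome biogenesis, amino acid response and glycolysis genes were called higher (camera, adjusted p = 0.000452, 0.00339, 0.00391, 0.00123 and 0.0355, in this order), with medians from 0.14 to 0.23. With an estimated correlation none was called (adjusted p = 0.445, 0.513, 0.445, 0.445 and 0.499 with an estimated correlation), and no member of the first 3 lists passed over all genes. Of 43 G1/S and replication genes, 37 lay above 0 with a median of 0.14. TIPIN and SLBP had the smallest p, at 9.38 and 41.4 FPKM in wild type against 16.1 and 55.5 in knockout. TIPIN lies in the shifted region of chromosome 15, and the run of 50 tested genes that holds SLBP (chromosome 4, 53285 to 4248242) had medians of 0.22 and 0.18 in knockout replicates 1 and 2. The 28 homologous recombination and Fanconi genes had a median of 0.16, which was 0.43 in knockout replicate 1 and -0.02 in replicate 2. The median GC content of this list was 41.5%, in the range where knockout replicate 1 stood apart, and the list was still called with length and GC corrected (camera, adjusted p = 0.0198). In it FANCI stood at 17.7 against 25.5 FPKM and XRCC2 at 4.11 against 5.97. Among 35 ribosome biogenesis genes, with a median of 0.17, WDR43 stood at 15.2 against 24.1 and NPM1 at 493.6 against 722.9 FPKM. Of 27 ATF4 and amino acid response genes, SLC7A11, the cystine transporter, rose from 5.54 to 13.6 FPKM. Of 38 glycolysis and hypoxia genes, ADM, encoding adrenomedullin, rose from 23.6 ± 1.97 to 56.3 ± 1.10. Leaving out knockout replicate 2 ended the calls for replication, ribosome biogenesis and amino acid response genes, and leaving out knockout replicate 1 those for recombination and for glycolysis and hypoxia genes. The glycolysis call was also lost without wild type replicate 1 or 2 (camera, adjusted p = 0.114 and 0.185), with the replicate block (adjusted p = 0.137), a pseudocount of 0.1 (adjusted p = 0.0514), median-ratio scaling (adjusted p = 0.0563), quantile normalization (adjusted p = 0.151) and group weights (adjusted p = 0.0561). Adjusted over the list alone, none of the replication, recombination or ribosome biogenesis genes was called, against 2 higher and 1 lower in the amino acid list and 1 higher and 1 lower in the glycolysis list.

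The immediate-early genes, which can respond to sample handling but also to other stimuli, were called lower (camera, adjusted p = 0.0299). The list was not called with an estimated correlation (camera, adjusted p = 0.688 with an estimated correlation). The call was also lost with knockout replicate 2 left out (camera, adjusted p = 0.555), with length and GC corrected (adjusted p = 0.104), at a mean FPKM of at least 5 (adjusted p = 0.0675) and with the shifted regions of chromosomes 10 and 15 left out (adjusted p = 0.0564), though not with those of chromosome 1 left out too (adjusted p = 0.0288). Their median was -0.02 in knockout replicate 1 and -0.39 in replicate 2. Of the 30 tested, DUSP5, a phosphatase of ERK, fell from 107.5 to 35.2 FPKM (1 rose and 5 fell adjusted over the list alone). The remaining lists were not called in the fit reported, and the alternatives that called one are given with it. Of 25 histone genes, HIST1H1C and HIST1H2BK fell, from 62.8 ± 1.35 to 29.9 ± 1.26 and from 74.96 ± 0.101 to 37.5 ± 3.87 FPKM (camera for the list, adjusted p = 0.143), and 1 rose and 6 fell adjusted over the list alone. Since RNA was purified on poly(T) beads, histone transcripts without a poly(A) tail were selected against. Some may have been carried over, as 18S ribosomal RNA was, at 1507 to 3481 FPKM in the 4 libraries. The histone values therefore do not measure total histone mRNA. The histone median was -0.42 in knockout replicate 1 and 0.06 in replicate 2, and the list was called lower with replicate 2 left out (camera, adjusted p = 0.000486) and at a mean FPKM of at least 5 (adjusted p = 1.71e-05). Of 27 TGF-beta genes, INHBA and TGFBI rose (camera, adjusted p = 0.650), and 4 rose and 2 fell adjusted over the list alone. The list's median of -0.12 differs in sign from its mean of 0.08 and from the test. Of 25 p53 target genes, GDF15 fell from 5.94 to 0.993 FPKM (camera, adjusted p = 0.919), and 1 rose and 2 fell adjusted over the list alone. Of the other NAT subunits, 11 tested, none passed (camera, adjusted p = 0.316), with NAA15 at 12.1 against 17.96 FPKM. Of 11 arginine methyltransferase genes none passed (camera, adjusted p = 0.650), with PRMT6 at 8.63 against 5.13. None of the 24 YAP/TAZ targets passed over all genes (camera, adjusted p = 0.230), and 3 rose and 2 fell adjusted over the list alone. The median of 0.08 goes with the test, while the mean of -0.0034 lies below 0. With the shifted regions of chromosomes 10 and 15 left out, ANKRD1 and MYOF among them, the list was called higher (camera, adjusted p = 0.0385), as it was with those of chromosome 1 left out too (adjusted p = 0.0260). In that list ANKRD1 stood at 114.6 ± 0.718 against 32.7 ± 14.8 FPKM. No member passed among 40 mitosis genes (camera, adjusted p = 0.136) or 76 cytosolic ribosomal protein genes (camera, adjusted p = 0.136). The ribosomal protein median was -0.18 in knockout replicate 1 and 0.21 in replicate 2, and the list was called higher without replicate 1 and lower without replicate 2 (camera, adjusted p = 6.05e-12 and 0.000566). With length and GC corrected it was called higher (camera, adjusted p = 0.0185). No member passed among 43 respiratory chain genes (camera, adjusted p = 0.479, and lower with knockout replicate 2 left out at adjusted p = 0.00147), 27 BCL2 family and caspase genes (camera, adjusted p = 0.230), 22 unfolded protein response genes (camera, adjusted p = 0.283), 19 heat shock genes (camera, adjusted p = 0.633) or 8 HOX genes (camera, adjusted p = 0.738). The cancer-testis list had 1 tested member, PAGE5, which fell from 1.83 to 0.226 FPKM.

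Of the genes tied to NatD in published work, FOXA2 fell, as given above. MMP14, a membrane-anchored matrix metalloprotease, stood at 198.3 ± 0.247 FPKM in wild type and 124.6 ± 28.7 in knockout, a log2 fold change of -0.68 ± 0.18 that did not pass over all genes (limma, adjusted p = 0.179). SNAI2, the EMT transcription factor Slug, stood at 22.3 ± 0.234 in wild type and 40.8 ± 10.4 in knockout (log2 fold change 0.82 ± 0.20, limma adjusted p = 0.139). Adjusted over the list alone, 1 rose and 2 fell, and since work on these libraries may have picked genes of this list, that count is not independent evidence of their direction. The list as a whole was not called (camera, adjusted p = 0.136), but it was called lower with wild type replicate 1 or 2 left out (camera, adjusted p = 0.000282 and 0.000437) and with the replicate number as a block (adjusted p = 0.000254).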

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

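Of the alternatives below, the length and GC correction, the group weights and the 2 fits without shifted chromosome regions were chosen after the data had been seen, and the others before. The 117 calls kept their direction in 18 of 18 refits, wherever the gene was still tested, but not their number. Much of this agreement in direction was fixed in advance. Another filter or variance prior, the replicate block, group weights and leaving out regions give the same fold change by construction. A gene whose groups do not overlap also cannot change direction when 1 library is left out. The count of changed genes was 0 without a filter (limma, 2272 genes at an unadjusted p under 0.05), 48 at a mean FPKM of at least 5, 233 with median-ratio scaling, 12 after rescaling to TPM, 262 after quantile normalization, 349 with length and GC corrected and 437 with group weights. Without the shifted regions of chromosomes 10 and 15 it was 93, with 93 of the 107 calls outside them kept, and without those of chromosome 1 too it was 82, with 82 of 101 kept. Pseudocounts of 0.1 and 0.5, no variance trend, a robust prior and a minimum log2 change of 1 gave 97, 113, 96, 106 and 115. The cause of these shifts was not tested. Leaving out 1 library at a time gave 81 to 6548 changed genes. The lone library left in a group is then assumed to vary like the other group, and without knockout replicate 1 (5585 genes, 35.5% of them higher) or 2 (6548 genes, 53.8% higher, against 22.2% of the 117) the spread is that of the tight wild type pair. Those fits kept 117 of the 117 calls, while leaving out wild type replicate 1 or 2 kept 70 and 65. The replicate number as a block gave 695 genes. The labels do not say that the numbers pair libraries, and the deviations of replicate 1 from the group means correlated at 0.13 between the groups. For NAA40 the log2 fold change ranged from -0.58 to -0.20 with single libraries left out, and it passed the threshold only without knockout replicate 2 (limma, adjusted p = 2.70e-05, against 0.1264 to 0.9999 in the other 17 alternatives). The number of lists called was 14, but 0 with an estimated correlation and 1 with fry. The estimated setting rests on 2 residual degrees of freedom, so its 0 does not tell whether correlation made the 14 calls. The cholesterol list lost its call there (camera, adjusted p = 0.445) although its estimated correlation of 0.0016 lay below the preset 0.01. With single libraries left out the lists called were not all the same ones. Without knockout replicate 1, and likewise without knockout replicate 2, more of the 14 calls were kept than lost. The calls lost are given with each list above. The number of lists called was 13 in each fit without shifted regions, where 12 of the 14 lists kept their call. Of the 80 genes other than NAA40 taken by the fixed rule, none changed direction in the alternatives that refitted them, although 65 were tested at a mean FPKM of at least 5, 79 with length and GC corrected, and 65 and 62 without shifted regions. The groups of these genes did not overlap, so their unchanged direction was also largely fixed in advance. Genes named after their values were seen are covered only where they are among the 117 calls. Count models were not run, since the values are FPKM. Depth is unknown, so whether the wild type libraries differ by more than sampling noise could not be examined.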

Other observations

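The tests on gene families, on HLA copies, on unedited cells, on shifted chromosome regions and on the splits were chosen after the results they bear on had been seen, and the other tests of explanations before. Among the latter, the test of chromosome segments with the length and GC trend removed took the result before the removal as its starting point. A search over gene families grouped tested genes by the letters that start their symbol. It asked which of 541 families with at least 4 tested members held more called genes than the rest (one-sided Fisher's exact test, Benjamini-Hochberg over 1082 tests). Of these tests 2 passed. These tests count near-identical copies, such as HLA-DRB1 and HLA-DRB5, as separate genes. The HLA family had 7 of 15 members that fell (adjusted p = 5.52e-09), and the cystatin family had 4 of 6 (adjusted p = 2.07e-05). Beside CST1 and CST4, the fallen cystatins were CST2, listed at 3.64 and 4.01 FPKM in wild type against 0.394 and 0 in knockout, and CST7, which went from 8.51 and 8.14 FPKM to 1.52 and 0.898. CST6 lay the other way, at 15.7 and 14.5 FPKM in wild type against 52.4 and 34.2 in knockout, without passing (limma, adjusted p = 0.0548). CST1, CST2 and CST4 are near-identical neighbours on chromosome 20, so their reads could not be assigned with certainty and they are not independent calls.

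Of the called genes outside the fixed lists, 5 that fell are given here, chosen after their values were seen. CXCR4, the receptor of the chemokine CXCL12, went from 7.26 and 6.94 FPKM to 1.09 and 0.871. The endothelial-type adhesion molecule gene ESAM went from 48.1 and 47.6 FPKM to 9.87 and 8.46, and LOXL4, a lysyl oxidase that cross-links collagen, from 78.7 and 79.4 to 21.2 and 13.5. WNT7B went from 9.35 and 10.1 FPKM to 2.39 and 2.28, and the secreted protease gene HTRA1 from 31.2 and 32.6 to 10.9 and 10.5. These 5 genes passed with limma adjusted p between 0.00920 and 0.0226, and the locus of ESAM holds 1 other listed gene. LOXL4 and HTRA1 lie in the region of chromosome 10 that was lower in both knockout libraries (medians of -0.35 and -0.53). Of the other 2 splits of the 4 libraries into 2 and 2, the highest called 0 genes against 117 for knockout against wild type, and the real split was the only 1 of 3 with as many. With 3 splits a share under 0.05 cannot be reached. Each other split also puts 1 wild type and 1 knockout library in each group. Any difference between the 2 pairs, whatever its source, then counts as spread, so few calls were to be had there. The comparison of splits therefore says nothing about the source of the 117 calls.

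The 2 regions of chromosomes 10 and 15 that lay shifted in both knockout libraries kept their shift once length and GC content were corrected. The corrected medians were -0.39 and -0.39 on chromosome 10 and 0.32 and 0.35 on chromosome 15. After this correction 4 regions met the same rule, those 2 and 2 on chromosome 1, both higher, with corrected medians of 0.24 and 0.41 in the first and 0.23 and 0.38 in the second. Of the 117 called genes, 16 lay in the 4 regions, and with the genes of these regions left out 82 genes were called. In 100 shuffled gene orders the corrected values gave 0 such regions. Since shuffling breaks every likeness between neighbouring genes, this count does not bear on the cause of the shifts. Copy number was not measured on DNA, so a difference in it between wild type and knockout cells stays open.

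Of 9 tested genes in the set of MHC class II genes, CD74 and CIITA, 8 were called lower, CIITA itself among them. The set was chosen after the data had been seen and is therefore given as a count without a test. Shared reads between HLA-DRB copies are argued against as the whole of these falls, since HLA-DRA, HLA-DMA, HLA-DMB, HLA-DPA1 and CD74 had a median log2 fold change of -2.13 with the weakest at -1.76. Loss of the whole segment between HLA-A and HLA-DPB1 (chromosome 6, 29942470 to 33089696) is also argued against. The 93 other tested genes there had a median of -0.12 (bootstrap 95% interval -0.19 to -0.05), with 2 called lower and 0 higher. The run of 50 tested genes from 31739948 to 33206831, class II genes included, had medians of -0.27 and -0.22 in knockout replicates 1 and 2. A smaller loss around the class II genes was not tested. A candidate explanation is lower expression of CIITA, the transactivator of these genes, whose log2 fold change was -1.26 ± 0.18 (limma, adjusted p = 0.0471). It remains a hypothesis, and a difference between the cells from which wild type and knockout cultures were grown stays open beside NatD itself.

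The knockout libraries differed from each other more than the wild type libraries did. Counting noise from lower depth is argued against, since among 716 genes with a mean FPKM of at least 100 the knockout pair's spread was still 5.03 times that of the wild type pair (bootstrap 95% interval 4.46 to 5.69). A smooth trend on length and GC content explained 32.9% of the variance between the knockout libraries and 3.52% between the wild type libraries. After its removal the ratio of spreads was 2.39 (2.27 to 2.50), against 2.86 before. The bias that this trend captures may thus be part of the difference but is not the whole. Since the trend rests on the longest transcript of each gene name, a length or GC bias that it misses stays open. Runs of 50 neighbouring genes explained 17.5% of the variance above shuffled order, which alone leaves gain or loss of chromosome segments open, but 2.70% once the length and GC trend was removed, which argues against segments as the main source of the difference between the 2 knockout libraries, though not against segments shifted alike in both. Separate clones or guide RNAs for the 2 knockout libraries would be a biological explanation, which the labels do not give and which was not tested.

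NAA40 mRNA remained at 62.8% and 85.8% of the wild type mean in the knockout libraries. Unedited cells could keep NAA40 mRNA in a mixed culture, but they would also keep the transcripts that fell in the knockout libraries. The 12 genes with the largest fall kept a median of 6.51% of the wild type level in knockout replicate 1 and 4.39% in replicate 2, and at most 17.1% and 12.4%. A share of unedited cells as large as the NAA40 level is therefore argued against, as long as those cells express these genes as wild type cells do. An edit that leaves the mRNA in place stays open, since the reads that would show it were not used here.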
